A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

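RNA of Schizosaccharomyces pombe (fission yeast) was measured on whole-genome tiling arrays in 3 low zinc and 3 high zinc replicates. Per the labels' protocols, cells grown in Edinburgh minimal medium were moved to LZM, a zinc-limiting medium with the chelators EDTA and citrate, and harvested after 4 hours. The zinc supplement was 0.003 mM in low zinc and 3 mM in high zinc, and total RNA was extracted with hot acidic phenol. Per the series' design text, RNA was labelled through an antibody against RNA/DNA hybrids. Each replicate was hybridised to 2 array designs, so that the 12 arrays made 6 replicates, and the arrays of a replicate were joined before any test. Array 1 held chromosome I and the first 747 kb of chromosome II, and array 2 held the rest.

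Per the file headers, the scanner files are 1-colour (Cy3) output of Agilent Feature Extraction 9.5.1.1, from scans with an extended dynamic range. Their processed values are intensity on a linear scale, per the file headers background-subtracted and detrended within each array, with low values replaced by a surrogate, and not scaled between arrays. The raw mean of each spot and the median of its local background are also deposited as intensity. The deposited spot flags (well above background, saturated, outlier) hold another kind of value, 0 or 1, as set by the scanner software per the file headers. The deposited value tables are log2 values, and comparison with the scanner files showed each column to be log2 of the processed intensity of the same array, matched by spot number, with no scaling or centring. Their medians ran from 11.5 to 12.2, and a sample's values differed from the scanner values by at most 5e-07.

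Log2 of the processed intensity, less each array's own 75th percentile over fission yeast probes, was the level used throughout. A level of 0 is therefore the 75th percentile of an array. Control spots were left out, as were 10404 of 458566 probes with an outlier flag on at least 1 array; saturated spots were kept. Between 98.7% and 99.9% of the fission yeast probes of an array were well above background, against 7.86% to 28.7% of the zebrafish control probes. The median processed intensity of an array ran from 2897 to 4798, and the number of arrays limits the precision. The brightest probes levelled off near 6.07, so changes of the most abundant RNAs can be understated.

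Probes were 60 bases long and started every 55 bases on each strand. The genome build of the array coordinates is not given in the sources used here, and all coordinates are the array files' own. Chromosome sequence was assembled from the overlapping probes, with 1040 bases of chromosome I, 2080 of chromosome II and 1140 of chromosome III not covered. Gene names and the start and end of each gene came from a table of assembly ASM294v3. Its coordinates were shifted, by at most 3000 bases, onto those of the array files. The shifts came from 113 anchors at which a gene's shifted ends met the start and stop codon of an open reading frame in the assembled sequence. Strand came from the longest frame, which had to reach 150 bases and, to settle the strand alone, 2 times the length of the longest frame of the other strand. The direction of the other genes of a cosmid settled the remaining strands. Among genes with a clear frame, the frame and the direction of the cosmid gave the same strand for 96.1%. That direction was taken from these same genes, in cosmids where at least 80% of them agreed. The share is therefore no independent check, and it does not cover genes whose frame left the strand unclear. In this way 4780 of the table's 5113 coding genes were kept, and 330 were left out because their strand was unclear or their frame was too short. The longest frame held a median of 61.9% of a kept gene's span, against 20.3% after displacing genes. Non-coding RNAs had no strand in the table and were not analysed here, so the part of the naming rule on them could not be used.

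Probes of 1 strand's sequence read RNA of the other strand. With that reading, the mRNA strand was the brighter for 96.0% of 4308 genes, by a median of 2.35 log2. A sense feature was the mean over the probes reading a gene's mRNA strand. An antisense feature was the mean over probes reading the opposite strand within the gene's longest frame. Probes within a coding gene of that opposite strand were left out. The 2 features of a gene can therefore cover different stretches of it. Features needed 3 probes and, in at least 3 replicates, 50% of probes well above background, which removed 0 sense features and 4 antisense features. This left 4778 sense and 4304 antisense features, with medians of 31 and 18 probes. Probes with a second match in the genome, of at least 50 bases at 90% identity, numbered 23030 and were kept. Genes whose probes nearly all have such a match are called uncertain.

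Differences were tested with limma (lmFit and eBayes, without a block), low zinc minus high zinc, with Benjamini-Hochberg adjustment over sense and over antisense features and a threshold of 0.05. Gene lists were tested on the sense features with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 19 lists. Single values of 3 against 3 replicates were also put to an exact two-sided permutation test, whose smallest p is 0.1. This test takes the replicates as exchangeable, without their pairing. The comparisons, the lists and the rule for named genes were fixed before the data were examined. The rule took adh1, adh4 and every measured zinc gene. It also took the 10 largest sense rises and falls and the 8 largest antisense rises and falls, among genes past the threshold whose groups did not overlap, and in each list the 4 members with the smallest adjusted p. List members missing from the name table were vel1, glk1, ald1, dur3-1 and erg13, and some others had no measured feature, among them 23 ribosomal protein genes.

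On simulated data with the real levels and spreads, the sense test recovered 64% of features changed by 0.5 log2, 94% of those changed by 1 and 100% of those changed by 2. It called 0.153% of the unchanged features. The antisense test recovered 40%, 90% and 100%, and called 0.0487% of the unchanged features. A list lowered by 0.5 log2 was called, and 0 of 18 unchanged lists were. The simulated genes varied independently, so this does not cover lists whose genes vary together: in the real data, splits of the replicates that mixed the groups called 5 to 11 lists at the preset correlation.

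Groups share replicate numbers, and the deviations of same-numbered sense profiles from their group means correlated at 0.242, 0.155 and 0.457, all over 0.1, so the numbers pair the replicates. That pairing comes from the data and not from the labels, and it includes the scan day, since replicates 1 and 2 were scanned on day 1 and replicate 3 on day 2. For antisense features the correlations were -0.195, 0.189 and 0.346. Replicates 1 and 3 of a group lay on the same slides, scanned on different days, so each slide held 1 group. Whether these slides were used again or held several arrays is not known here. The SDs and limma tests count the 2 replicates as independent, which was not shown. Alternatives were the replicate number, the scan day or the slide as a block; normexp background correction with an offset of 50; quantile, median or no scaling; the percentile over detected probes; medians over probes; and other filters, thresholds and single arrays. Each replicate was also left out in turn. Computation used R 4.3.3 with limma 3.58.1, Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 for second matches.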

Results

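Sense and antisense RNA of fission yeast was measured over the whole genome in cells held for 4 hours in low zinc or high zinc medium. The groups held 3 replicates each, every replicate on 2 arrays, and the number of arrays limits the precision. Levels are log2 intensities relative to the 75th percentile of each array, and changes are low zinc minus high zinc on that scale. Sense levels correlated between replicates of a group at 0.986 to 0.996, and at 0.901 to 0.917 across the groups. Antisense levels correlated at 0.942 to 0.985 within groups and at 0.830 to 0.878 across them. Adjusted p-values are from limma, and an exact permutation test of 3 against 3 replicates cannot give a p under 0.1. For each feature whose change is printed as that of a named gene, the 3 replicates of each group were separated without overlap, except the sense features of zhf1, pcs2, pho84 and SPCC13B11.02c and the antisense features of pcs2 and zrt1.

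The first comparison asks how zinc affects the antisense transcript of adh1, which the series title names. In low zinc the mRNA of adh1, the main alcohol dehydrogenase of fermentation, gave way to RNA of the opposite strand. The adh1 sense level was -0.05 ± 0.07 (SD, n = 3) in low zinc and 5.45 ± 0.06 in high zinc, and so it fell by 5.50 (SE 0.071), which is 45.4-fold. The antisense level over the longest frame of the same gene was 5.12 ± 0.25 in low zinc and -1.86 ± 0.17 in high zinc. That is a rise of 6.97 (SE 0.147) or 126-fold. Both bright levels lay near the top of the range of the arrays, so the size of these changes can be understated. The mRNA of adh4, another alcohol dehydrogenase, rose by 4.06 (SE 0.109), from 0.63 ± 0.11 to 4.70 ± 0.19, or 16.7-fold.

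The gene adh1 (SPCC13B11.01) lies on the plus strand of chromosome III between 1592192 and 1593789, read by 26 sense and 18 antisense probes, none with a second match in the genome. Antisense signal rose by 3 log2 or more in low zinc along a stretch of 3580 bases, from 1590766 to 1594345, except at 3 probes. This stretch of the minus strand averaged 5.01 ± 0.11 over 64 probes in low zinc and -1.50 ± 0.12 in high zinc. It reached past the 5′ end of adh1 from 1592145 to 1590766, where 25 probes averaged 4.79 in low zinc and -1.13 in high zinc. Past the 3′ end it covered 1593791 to 1594345, where 10 probes averaged 4.62 and -0.33, and it ended over SPCC13B11.02c, a minus-strand gene whose 3′ end lies at 1594302. Directly past the 3′ end of adh1, from 1593790 to 1594301, the plus strand fell by 1.72. Over wider windows it was higher in low zinc on average, by 2.50 over 1589226 to 1592145 and by 2.25 over 1593791 to 1596765. The antisense feature of SPCC13B11.02c, on the plus strand, rose by 4.35 (SE 0.15, adjusted p = 5.45e-22), while its sense change was 0.18 (adjusted p = 0.240).

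The adjusted p was 1.39e-08 for adh1 sense, 2.04e-28 for adh1 antisense and 3.48e-07 for adh4 sense. Both adh1 values gave an exact permutation p of 0.1, the smallest possible when the pairing of the replicates is ignored. Keeping the pairs would leave fewer orders, so the smallest p would be larger. Within scan day 1 the adh1 changes were -5.54 for sense and 7.05 for antisense, and within scan day 2, with 1 replicate per group and no test, they were -5.44 and 6.82. With scan day as a block the estimates were unchanged at -5.50 and 6.97.

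**Figure D1:**
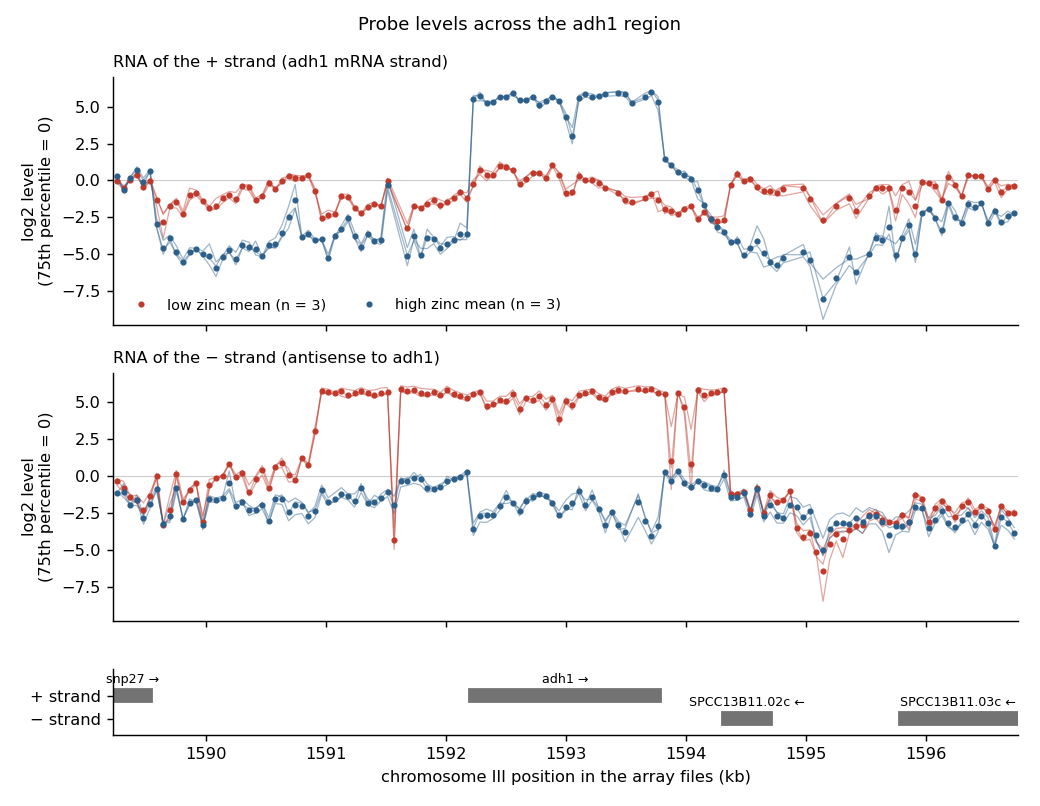
Levels of the probes of each strand along chromosome III around adh1 (log2 relative to the 75th percentile of each array, means of 3 replicates per group) with the genes placed there. The minus strand averages 5.01 in low zinc from 1590766 to 1594345, where 3 of 64 probes did not rise by 3 log2 or more, and the plus strand over adh1 averages 5.45 in high zinc and -0.05 in low zinc.

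Sense RNA was then compared over all coding genes. The largest rises in low zinc were those of 3 near-identical subtelomeric genes, SPBC1348.06c with 10.04, SPAC977.05c with 9.95 and SPBPB2B2.15 with 9.91. All their probes match the other copies, so which of them rose is uncertain. They were followed by shu1 with 9.45 (SE 0.21) and str3 with 9.42 (SE 0.30), which take up haem, and by the ferric reductase gene frp1 with 5.89 (SE 0.13). In high zinc shu1 and str3 were at -5.88 and -5.89. That is close to -6.30, the level that 95% of the zebrafish control probes stay under, so the size of their rises is uncertain. SPAPJ695.02 rose by 5.46, the dihydroxyacetone kinase gene dak2 by 4.26, SPBPB2B2.06c by 4.24 and the iron and zinc transporter gene fet4 by 4.19. The largest fall after adh1 was that of mug14, which fell by 3.28, ahead of the catalase gene ctt1 with -3.27 and SPBPB10D8.01 with -3.02. In low zinc mug14 and SPBPB10D8.01 were at -5.51 and -5.70, also close to that level of the control probes, so the size of their falls is uncertain. The glutamate synthase gene glt1 fell by 2.77, the vacuolar iron transporter gene pcl1 by 2.75, tim18 by 2.69, the cyclophilin gene wis2 by 2.49, the cytochrome c gene cyc1 by 2.46 and SPAP14E8.05c by 2.37.

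Of 4778 sense features, 963 were higher and 1454 lower in low zinc, and 2361 did not pass the test; 173 were higher and 117 lower by at least 2-fold. The groups did not overlap for 61.1% of features, against 10% by chance if the replicates are taken as exchangeable, without their pairing. The split of calls depends on the scaling, which moves the median change of all genes: it was -0.06 here, -0.14 with quantile normalization (824 higher, 1902 lower), -0.40 with scaling to the median of each array (321 and 3042) and 0.07 in the deposited values without scaling (1102 and 750). Within scan day 1, with 2 replicates per group, 603 features were higher and 951 lower; with scan day as a block 1437 were lower and 40.5% of the calls were higher. Scan day 2 held 1 replicate per group and gave no count.

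**Figure D2:**
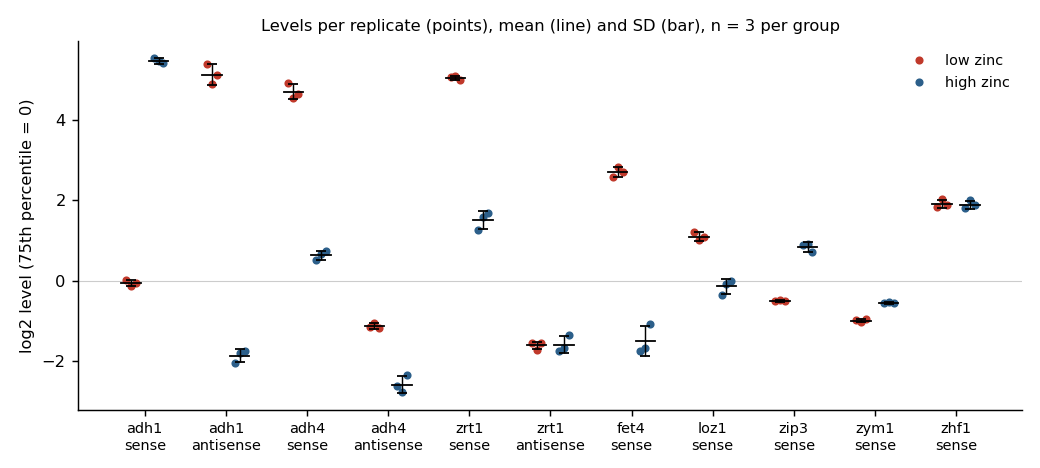
Sense and antisense levels of named genes in each of the 6 replicates (log2 relative to the 75th percentile of each array); points are replicates, lines the group means and bars the SD. The 3 low zinc replicates of adh1 lie near -0.05 for sense and 5.12 for antisense, and the 3 high zinc replicates near 5.45 and -1.86.

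Some genes of metal uptake, such as shu1, str3, frp1 and fet4, were among those that changed most. In the zinc list, 8 of 14 measured genes rose and 3 fell. The plasma membrane zinc transporter gene zrt1 rose by 3.53 (SE 0.11, adjusted p = 7.18e-07), gcd1 by 1.65, the zinc-responsive repressor gene loz1 by 1.24 and the transporter gene zip2 by 0.87. Besides adh1, the transporter gene zip3 fell by 1.34 and the metallothionein gene zym1 by 0.44. The values for the zinc transporter genes zhf1 and cis4 were 0.02 (adjusted p = 0.865) and -0.14 (adjusted p = 0.151), and that for pcs2 was -0.07 (adjusted p = 0.682). With scaling to the median of each array zhf1, cis4 and pcs2 had -0.30, -0.47 and -0.39 and passed the test, so that 8 rose and 6 fell, and in the deposited values zym1, with -0.26, did not. The list rose by camera (adjusted p = 0.00753; adjusted p = 0.295 with an estimated correlation), but without probes that have a second match, and so without SPAC977.05c and SPBC1348.06c, its adjusted p was 0.0556. Its members were partly chosen from published work on zinc in this yeast, possibly on these samples, so the list is not independent evidence of its direction.

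All 15 iron genes passed the test, 13 higher and 2 lower, with a median change of 3.04 (camera adjusted p = 1.62e-09; adjusted p = 0.295 with an estimated correlation). Beside shu1, str3 and frp1, the iron permease gene fip1 rose by 4.15 and the oxidase gene fio1 by 3.88, the siderophore transporter gene str1 by 3.32, and sib2 and sib1 of ferrichrome synthesis by 3.05 and 2.10. The 2 that fell were pcl1 and fep1, the iron-dependent repressor gene, which fell by 0.70. In the copper list 5 of 8 rose and 2 fell (4 and 3 with scaling to the median of each array). The copper transporter genes ctr4 and ctr5 rose by 2.62 and 1.56 and the copper pump gene ccc2 by 1.27, while sod1, encoding the copper and zinc superoxide dismutase, fell by 1.93. The copper list's camera adjusted p was 0.0426, and it was 0.295 with an estimated correlation, 0.0647 with the replicate number as a block, 0.0514 with scan day as a block and 0.0658 without low zinc replicate 1. Over all alternatives its adjusted p ran from 0.000568 to 0.909. For these 3 lists the counts adjusted over the list alone were the same.

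Both strands rose for kilobases around several of these abundant genes. Of the 51 genes that rose by at least 2 log2, 24 lay within 5000 bases of an abundant gene that also rose, 20 of them on the opposite strand to it. These are not 24 separate neighbours: 12 lie beside the 3 near-identical copies and have such copies themselves, so they are uncertain, and 8 are themselves among the abundant genes, as fio1 beside fip1. The remaining 4 were eno102, a member of the glycolysis list, with 2.30, and, named after their values were seen, ght3 with 2.13, hhy1 with 2.62 and SPBPB21E7.05 with 2.85. In high zinc SPBPB21E7.05 lay under -6.30, the level that 95% of the zebrafish control probes stay under, so the size of its rise is uncertain.

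**Figure D3:**
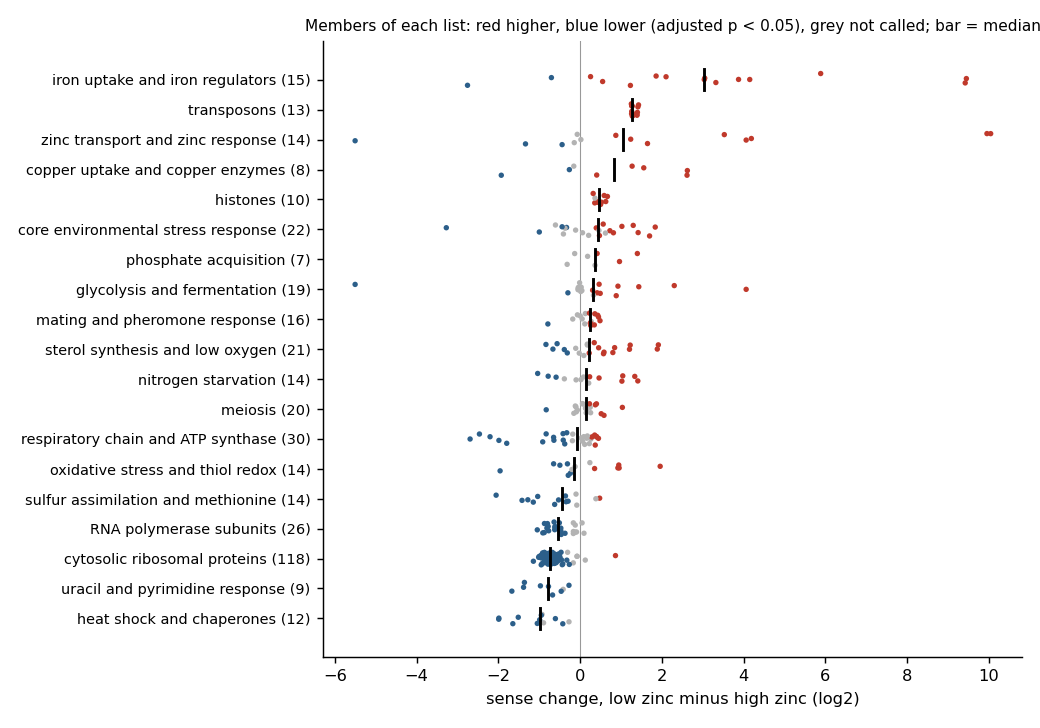
Sense changes of the members of each gene list (log2, low zinc minus high zinc); each point is a gene, red if higher, blue if lower and grey if not past the test, and each bar the list's median. The iron list has a median of 3.04 and the ribosomal protein list a median of -0.73.

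In 5 lists most measured genes were lower in low zinc: ribosomal proteins, RNA polymerase, heat shock, uracil and pyrimidines, and sulfur assimilation. Of 118 cytosolic ribosomal protein genes, 112 fell and 1 rose, with a median of -0.73; adjusted over the list alone, 113 fell and 1 rose. Examples are rpl2702 with -1.14, rpl2001 with -1.001, rps101 with -0.86 and rpl3602 with -0.82, and the gene that rose was rpl1802 with 0.87, named after its value was seen. Of 26 RNA polymerase subunit genes 18 fell and 0 rose (19 and 0 adjusted over the list alone), led by rpa2 with -1.05, rpc40 with -0.91, rpc17 with -0.87 and rpc31 with -0.80. Of 12 heat shock and chaperone genes 9 fell and 0 rose in either adjustment, among them the mitochondrial chaperonin gene mcp60 with -1.99, mas5 with -1.65, ssc1 with -1.05 and ssz1 with -0.99. Of 9 uracil and pyrimidine genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), among them urg2 with -1.67, ura1 with -1.38, ura3 with -1.36 and urg3 with -0.67. Of 14 sulfur assimilation genes 10 fell and 1 rose (10 and 2 adjusted over the list alone), and the sulfate-activating enzyme genes sua1 and met14 had changes of -2.06 and -1.15, sir1 of -1.42 and met16 of -1.04. In the deposited values 6 sulfur genes fell and 2 rose, with a median of -0.29 in place of -0.44. These 5 lists had negative medians in every scaling tried.

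Camera's adjusted p was 7.07e-21 for ribosomal protein genes, 8.99e-05 for RNA polymerase, 0.00141 for heat shock, 0.000963 for uracil and 0.00753 for sulfur. With an estimated correlation the adjusted p was 0.295, 0.419, 0.443, 0.295 and 0.419 in the same order, so that none of these calls held. With scaling to the median of each array the heat shock and sulfur calls were lost too (adjusted p = 0.0559 and 0.0561); over all alternatives their adjusted p ran from 4.67e-07 to 0.443 and from 0.00162 to 0.453.

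Energy metabolism changed gene by gene. In the respiratory chain list 13 of 30 genes fell and 6 rose, also when adjusted over the list alone, without a call for the list (camera adjusted p = 0.283) and with a median of -0.08. In the deposited values 10 fell and 8 rose, the median was 0.04 and the list was called lower (adjusted p = 0.0333); with scaling to the median of each array 17 fell and 0 rose, with a median of -0.42. The genes of succinate dehydrogenase subunits sdh2 and sdh1 fell by 2.20 and 1.99, and tim18 and cyc1 fell as given above. In the glycolysis and fermentation list 9 of 19 rose and 2 fell, the same counts as adjusted over the list alone, and the median of 0.31 was -0.05 with scaling to the median of each array, where 5 rose and 5 fell. The enolase gene eno102 rose by 2.30 and the pyruvate decarboxylase gene pdc201 by 1.44; adh1 and adh4 are members too. Its camera adjusted p was 0.00753, with 0.453 from an estimated correlation, 0.0703 without low zinc replicate 1 and 0.797 on array 2 alone.

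Stress lists were mixed. In the core environmental stress list 10 of 22 rose and 4 fell (11 and 4 adjusted over the list alone): the calcium pump gene cta3 rose by 1.84, the fructose bisphosphatase gene fbp1 by 1.299 and tms1 by 1.02, while ctt1 fell. With scaling to the median of each array 6 rose and 6 fell, with a median of 0.08 in place of 0.43. The list's camera adjusted p was 0.0356, 0.5995 with an estimated correlation, 0.134 without low zinc replicate 1, 0.0916 without high zinc replicate 3 and 0.0535 over features whose mean level lay above that of the median probe. In the oxidative stress list 5 of 14 rose and 6 fell (5 and 7 adjusted over the list alone), and the median of -0.16 and the upward camera test (adjusted p = 0.654) differed in sign. The balance turned with the scaling, with 6 higher and 2 lower in the deposited values and 4 and 8 with scaling to the median of each array. In the main scaling the sulfiredoxin gene srx1 of this list rose by 1.96, the peroxiredoxin gene tpx1 by 0.95 and obr1 by 0.92. In the same scaling pmp20 fell by 1.96, and it had -1.27 within scan day 2, with no test.

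Among the remaining lists, all 13 transposon copies of Tf2 rose, by 1.25 to 1.43, but their probes match several copies, so single copies such as Tf2-13, Tf2-9, Tf2-11 and Tf2-10, with 1.39 to 1.43, are uncertain. Of 10 histone genes 9 rose and 0 fell (10 adjusted over the list alone), among them hht3 by 0.67, hta2 by 0.63, htb1 by 0.59 and hhf3 by 0.50, although 0 of them passed with scaling to the median of each array. Within scan day 2, with no test, hta2 had 0.38. Camera's adjusted p was 8.52e-11 for transposons and 0.000297 for histones, each with an adjusted p of 0.295 with an estimated correlation. Of 21 sterol and low oxygen genes 11 rose and 5 fell, in either adjustment (adjusted p = 0.0219; adjusted p = 0.453 with an estimated correlation), and the median of 0.22 was -0.13 with scaling to the median of each array, where 6 rose and 7 fell. They included erg32 with 1.91, the transcription factor gene sre1 with 1.89, osm1 with 0.84 and erg24 with 0.80. Of 7 phosphate genes 3 rose and 0 fell, in either adjustment, with a median of 0.37, while with scaling to the median of each array 2 rose and 2 fell with a median of 0.013. Those that rose were the acid phosphatase gene pho1 by 1.40, tgp1 by 0.96 and pho7 by 0.42, which was 0.06 (adjusted p = 0.602) with scaling to the median of each array. Within scan day 2, with no test, pho1 had 0.89. The phosphate transporter gene pho84 had 0.37 with an adjusted p of 0.0572, which was 0.0170 with the replicate block, 0.0142 with scan day as a block and 0.00263 without high zinc replicate 3, but with scaling to the median of each array its value was 0.013 (adjusted p = 0.937). The phosphate list's adjusted p was 0.0426, 0.453 with an estimated correlation, 0.0521 with the replicate block, 0.0549 in the deposited values, and 0.0675, 0.0789 and 0.0637 without low zinc replicate 3, high zinc replicate 1 and high zinc replicate 2; its range over all alternatives was 0.0121 to 0.453.

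Of 14 nitrogen starvation genes 6 rose and 3 fell, in either adjustment, without a call for the list (camera adjusted p = 0.0998; 0.0451 without low zinc replicate 2), and a median of 0.15. With scaling to the median of each array 4 rose and 6 fell, the median was -0.19, and the list was called higher relative to the other genes (adjusted p = 0.0176). The glutamate dehydrogenase gene gdh2 rose by 1.41, the ammonium transporter gene amt3 by 1.04 and the malic enzyme gene mae2 by 1.02, while put4 fell by 1.04. Mating and meiosis lists stood for other cell states. Of 16 mating genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), with mei2 at 0.49, mam2 at 0.45, sxa2 at 0.25 and mam4 at -0.79. The call of sxa2 was lost without low zinc replicate 3 or high zinc replicate 1 (adjusted p = 0.0768 and 0.0501), and its value turned to -0.01 with quantile normalization. That of mam2 was lost with quantile normalization, with scaling to the median of each array and within scan day 1 (adjusted p = 0.114, 0.2002 and 0.0595), and that of mei2 with scaling to the median (adjusted p = 0.189). Of 20 meiosis genes 6 rose and 1 fell (5 and 1 adjusted over the list alone), with rec12 at 1.03, rec8 at 0.52, mei4 at 0.37 and meu1 at -0.83. The calls of rec8 and mei4 were lost with quantile normalization (adjusted p = 0.258 and 0.0501) and with scaling to the median of each array (adjusted p = 0.252 and 0.874), and that of mei4 within scan day 1 (adjusted p = 0.073). Their medians of 0.24 and 0.14 turned to -0.02 and -0.16 with quantile normalization and to -0.09 and -0.19 with scaling to the median of each array. Under the latter 0 mating genes rose and 3 fell, and 1 meiosis gene rose and 6 fell. Camera's adjusted p was 0.0321 for mating and 0.0359 for meiosis; with an estimated correlation the adjusted p was 0.387 and 0.562. Both calls were lost with quantile normalization (adjusted p = 0.282 and 0.824), with scaling to the median of each array (0.0561 and 0.0873), in the deposited values (0.0549 and 0.0696) and within scan day 1 (0.0728 and 0.205). Without high zinc replicate 3 they were lost as well (adjusted p = 0.0751 and 0.156), and that of meiosis also without low zinc replicate 3 (adjusted p = 0.0507).

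Of the 19 lists, 11 were called higher and 5 lower with the preset correlation, and 0 with an estimated correlation, where 1 list, iron, had an unadjusted camera p under 0.05, at 0.0283. Within scan day 1 the count of called lists was 14, and with scan day as a block it was 15. With the replicate block it was 14.

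Antisense RNA was compared in the same way over coding genes. Large rises were those over adh1, with 6.97, and over shu1 and str3, with 7.27 and 6.88. The levels over shu1 and str3 in high zinc, -8.35 ± 0.79 and -7.56 ± 0.51, lay under -6.30, the level that 95% of the zebrafish control probes stay under. The size and rank of these changes are therefore uncertain, and that of shu1 was 5.41 with normexp background correction. Antisense features of SPBPB2B2.15, SPAC977.05c and SPBC1348.06c rose by 5.06, 4.69 and 4.69, again uncertain between copies, SPCC13B11.02c by 4.35 and SPAPJ695.01c by 3.86. In high zinc SPBPB2B2.15 and SPAPJ695.01c, at -6.30 and -6.31, were no brighter than that level of the control probes. Apart from adh1 and SPCC13B11.02c, these genes are ones whose sense RNA rose as well, or lie within the regions where both strands rose. In the zinc list, antisense rose over fet4 by 2.26, loz1 by 1.48, adh4 by 1.45, zip2 by 1.14, zhf1 by 0.53, cis4 by 0.47, pcs2 by 0.44 and gcd1 by 0.33, fell by 0.52 over zip3, and had a value of -0.01 over zrt1 (adjusted p = 0.930). Over zrt1 the value was -0.37 (adjusted p = 0.0376) with scaling to the median of each array and -0.43 (adjusted p = 0.00709) when antisense was centred on its own median, and over zip3 it was -0.34 (adjusted p = 0.0545) in the deposited values. The calls of zhf1, cis4, pcs2 and gcd1 were lost with quantile normalization, with scaling to the median of each array and when centred; with quantile normalization their values were 0.27, 0.14, 0.15 and -0.03. That of gcd1 was also lost without low zinc replicate 1 or 3 or high zinc replicate 1 or 2 (adjusted p = 0.174, 0.168, 0.0879 and 0.0652), and that of pcs2 without low zinc replicate 3 or high zinc replicate 1 or 2 (adjusted p = 0.105, 0.0957 and 0.116). Antisense fell over ctt1 by 1.57 and over SPBPB10D8.01 by 1.84, whose sense RNA also fell; the low zinc level over SPBPB10D8.01, -7.21, was under that of the control probes, and its change was -1.22 with normexp, so its size and rank are uncertain. Other falls were over guf1 with -1.43, SPAPB15E9.06 with -1.29, mug2 with -1.10, SPCC191.06 with -1.08, meu31 with -1.01 and hop1 with -0.98. Within scan day 2, with 1 replicate per group and no test, guf1 had -0.58 and SPCC191.06 had -0.60. With all opposite probes over the whole gene span, those inside neighbouring genes included, SPAPB15E9.06 had -0.80 and mug2 had -0.60.

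Of 4304 antisense features 2832 were higher and 79 lower in low zinc, 249 and 7 of them by at least 2-fold. For 69.3% the groups did not overlap, against 10% by chance without the pairing of the replicates. Over the 103 ribosomal protein genes with such a feature, 100 were higher and 1 lower, with a median of 0.95. The median antisense change was 0.43, and the scaling moved it. It was 0.11 with quantile normalization (900 higher, 279 lower), 0.09 with scaling to the median of each array (833 and 317) and 0.55 in the deposited values (3305 and 45). Centred on its own median, antisense had 607 higher and 516 lower features. The counts were 2739 and 104 within scan day 1, and 3148 and 100 with scan day as a block.

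The last comparison asks whether the exchange seen at adh1 was general. Only 6 genes had a sense fall and an antisense rise of at least 2-fold each, all called on both strands. Beside adh1 these were pcl1, which lies beside frp1, with -2.75 and 1.42, hsp90, a chaperone gene, with -1.51 and 1.46, the ribosomal protein gene rpl2001 with -1.001 and 1.20, tif51 with -1.10 and 1.16, and SPAC683.02c with -1.20 and 1.01. Both strands rose by at least 2-fold over 106 genes and fell over 2, and 0 genes had a sense rise with an antisense fall of that size. Without the 2-fold limit, 537 of 1329 genes called on both strands moved in opposite directions, 526 of them with sense down and antisense up, and 792 moved the same way. All these counts rest on the main scaling, in which the median antisense change was 0.43. It was 0.11 with quantile normalization and 0.09 with scaling to the median of each array. The balance of directions, and genes near the 2-fold limit, can therefore move with the scaling. Across 4304 genes the sense and antisense changes had a Spearman correlation of 0.512, with an SD of 0.0958 over the 9 pairs of a low zinc and a high zinc replicate. Over features whose mean level lay above that of the median probe it was 0.297. Genes are not independent replicates, and no p is given.

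**Figure D4:**
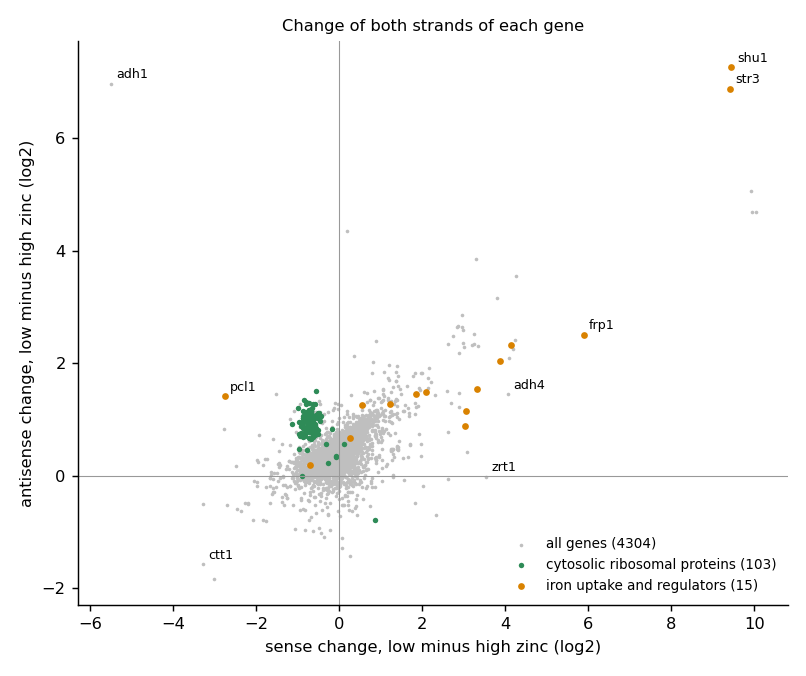
Antisense change against sense change of each coding gene with both features (log2, low zinc minus high zinc); each point is a gene, green for the 103 ribosomal protein genes and orange for the 15 iron genes. The point of adh1 lies at -5.50 for sense and 6.97 for antisense.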

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

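The comparison of the following probes with the zebrafish control probes was chosen after the main results had been seen. Signal was present on 3 kinds of probes that the comparisons of coding genes did not use, in each case set against the level that 95% of the zebrafish probes stay under, -6.30. Of the 690 mitochondrial probes 100% lay above that level, with medians of 2.48 in low zinc and 2.48 in high zinc. Of the 678 probes of the separate mating-type region sequence 84.7% lay above it, with medians of -4.70 in low zinc and -5.08 in high zinc. Of the 94041 probes between coding genes 96.2% lay above it, with medians of -2.87 in low zinc and -3.10 in high zinc.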

How the results depend on the processing

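Slide as a random block, scan day 1 only, scan day 2 only and antisense centred on its own median were chosen after seeing the data; the other alternatives were planned. Of 29 alternatives, each named-gene result was run under 22 to 25; under those, 98 of 119 kept their side of the threshold and, where called, their direction, and 3 reversed in at least 1. Scan day 2 alone has no test, and there 29 moved by more than the spread between replicates. The adh1 changes kept both in all they had: -5.86 to -5.44 for sense and 6.56 to 7.59 for antisense. Leaving out each replicate in turn gave 716 to 943 higher and 1147 to 1397 lower sense features, 2078 to 3180 and 57 to 100 antisense features, 13 to 17 lists and Spearman correlations of 0.448 to 0.537.

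Counts of calls moved with the scaling. Quantile normalization gave 900 higher and 279 lower antisense features. Scaling to the median of each array gave 321 higher and 3042 lower sense features and 833 and 317 antisense features. The deposited values gave 750 lower sense and 45 lower antisense features, and antisense centred on its own median gave 607 higher and 516 lower. These settings shift the median change, which their construction shows. Quantile normalization also reversed the meiosis list (adjusted p = 0.824, range over alternatives 0.0102 to 0.824), gcd1 antisense (-0.029) and sxa2 sense (-0.013). Scaling to the median of each array reversed gcd1 antisense (-0.018), sxa2 sense (-0.073) and zhf1 sense (-0.30), and centring gave -0.083 for gcd1 antisense. The cause of single reversals was not tested.

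Fewer features or arrays, and stricter limits, leave fewer features to call by construction. A minimum of 8 probes gave 50 lower antisense features. Array 1 alone gave 479 higher and 769 lower sense features, 1227 and 46 antisense features and 10 lists; array 2 alone gave 486, 685, 1591 and 34 features and 9 lists. On array 1 the copper, mating, meiosis and sterol lists lost their calls (camera adjusted p = 0.909, 0.0900, 0.489 and 0.324). On array 2 the zinc, core stress, sulfur, glycolysis and mating lists lost theirs (camera adjusted p = 0.117, 0.356, 0.453, 0.797 and 0.2002). Features whose mean level lay above that of the median probe gave 821 higher and 27 lower antisense features and a Spearman correlation of 0.297; for the correlation the cause was not tested. An adjusted p under 0.01 left 598 higher sense features, and a 2-fold limit left 173 higher and 117 lower sense and 249 and 7 antisense features. Scan day 1 alone, with 2 replicates per group, gave 603 higher and 951 lower sense features; the cause was not tested, and leaving out samples also raised some counts. Camera with an estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05.

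With the replicate number as a block, 1070 sense features were higher and 1575 lower, 3138 antisense features were higher and 99 lower, 14 lists were called, the adh1 changes were -5.50 and 6.97 and the Spearman correlation was 0.512. The block ended the calls of the copper and phosphate lists (adjusted p = 0.0647 and 0.0521) and gave pho84 a call (adjusted p = 0.0170); among lists and named genes it changed no other call. Slide as a random block gave 1112 higher and 1600 lower sense features. The correlation estimated within slides was -0.237 for sense and -0.394 for antisense features. As each slide held 1 group, a negative correlation lowers the error of the comparison. The larger counts therefore do not show that sharing slides is harmless. Signal near background limits the antisense changes of shu1 and str3, where 12.5% and 25.8% of probes were well above background in high zinc.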

Other observations

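The genes of this paragraph were chosen after their values were seen, and stand for no tested group. The carbonic anhydrase gene nce103 fell by 2.26, the aconitase gene aco1 by 1.66, the dihydroxy-acid dehydratase gene ilv3 by 1.67, the biotin synthase gene bio2 by 1.64, the ribosome recycling gene rli1 by 1.56 and zpr1, which encodes a zinc finger protein, by 1.61. Among genes that rose outside the lists, cmt2 had 3.79, aes1 2.95, mmt1 2.26 and the invertase gene inv1 1.98.

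Regions between coding genes were compared after the main results had been seen. Of 3493 such regions of a strand, 577 were higher in low zinc and 105 lower by limma, 205 and 19 of them by at least 2-fold. For 33.6% the groups did not overlap, against 10% by chance without the pairing of the replicates. The plus strand rose beside the haem uptake genes, by 7.14 between shu1 and str3 and by 6.80 between ght3 and shu1. In high zinc these regions were at -8.56 and -8.72, under the -6.30 that 95% of zebrafish probes stay under, so the size and rank of the rises are uncertain. The minus strand between SPBPB2B2.14c and SPBPB2B2.15 rose by 5.15 and the plus strand between SPAC977.05c and SPAC977.06 by 5.15, in near-identical sequence and from high zinc levels of -6.81 and -7.05, so both are uncertain. The lowest values were -2.36 for the plus strand between tim18 and SPBC29A3.21, -1.77 for the minus strand between SPBC36.01c and SPBC36.02c, and, on the plus strand, -1.72 between adh1 and SPCC13B11.02c and -1.49 between abc3 and mug14, where the low zinc level of -6.53 was under that of the control probes. Centred on their own median, 543 regions were higher and 629 lower.

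In the patterns weighed next, the tests on zebrafish probes, on the reach of the opposite strand and on second matches of adh1 probes were chosen after the result was seen; the others were set before.

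The first pattern is the exchange of strands at adh1 in low zinc. In replicate 2 alone, on slides used a single time, antisense rose by 6.67 and sense had -5.56. This was set as a test of signal left on re-used slides. Shared slides held only replicates of the same group, so signal left on them would resemble that group's own. The test therefore cannot decide on that cause, and no conclusion is drawn from it. It also does not show whether replicates on shared slides are independent. Of the 18 antisense probes 0 have a second match in the genome, which argues against RNA from another place. The values are consistent with a zinc-dependent antisense transcript running across adh1 and past both ends, as a hypothesis; whether it acts on the mRNA was not tested. The rise of the plus strand beside the gene, and what it adds, stays open.

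The second pattern is the antisense rise in low zinc at most genes. The 90th percentile of the zebrafish probes fell by 0.330 (SD 0.218 over same-numbered pairs), which argues against more non-specific signal in low zinc. Each antisense feature was matched to the sense feature nearest in level, which drew on 918 sense features, with repeats. Over these matches the median sense change was 0.150 (SD 0.0923), between the limits set for either outcome. The median antisense change exceeded that by 0.277 (SD 0.185). Both of these SDs are over the 9 pairs of a low zinc and a high zinc replicate. A rise of dim signals on either strand may thus account for part of it. It cannot be told apart from a change of antisense RNA, because no RNA added in known amounts was used for scaling here. A biological effect of zinc stays open, untested.

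The third pattern is the rise of both strands for kilobases around abundant genes whose mRNA rose, 17 genes with a rise and a level in low zinc of at least 2 log2. The strand opposite the gene rose by a median of 1.83 from 1 to 3 kb beyond the ends (lower quartile 1.13, 16 genes). Over 11 separate places, with copies and close neighbours joined, these values were 1.29 and 1.04. The median antisense change over all genes was 0.43. This argues against a fixed share of the gene's own mRNA being read by opposite probes. Probes opposite neighbouring genes were included, so the test cannot exclude a share of a neighbour's mRNA. RNA held by nearby sequence, such as through genomic DNA in the RNA, could make flanks bright beside any abundant gene. The limit set for this cause was a difference of over 2 log2. Beside 85 abundant unchanged genes the opposite strand was brighter than beside 356 dim genes by 0.483 (quartiles 0.0679 to 0.843). Unchanged here means without a call or with only a small change. The upper quartile too lies under that limit, and the quartiles cross the lower limit set against this cause. The rises to be explained, with medians of 1.83 and 1.29, are themselves under 2 log2. The test therefore cannot decide on this cause, and no conclusion is drawn from it. Beside the genes that rose this cause cannot be told apart from transcription of the flanks in low zinc. Transcription spreading from these genes in low zinc is the biological explanation left open.

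The 6 replicates can be split into groups of 3 in 10 ways, too few for a share under 0.05. For the sense features 1 split of 10, the real one, gave as many calls (2417; highest other 0), and for the antisense features likewise 1 (2911; highest other 0). For the regions between genes it was 1 (682; highest other 0), and for the gene lists 1 (16; highest other 11). The 3 other splits that part all pairs of replicate numbers called 11, 9 and 7 lists.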
